A study of Danio rerio with 4 samples.

How the data were processed

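Messenger RNA of whole zebrafish embryos (Danio rerio) at about 24 hours after fertilization was sequenced as polysomal mRNA and as total mRNA, each from wild-type embryos and from eif3ha morphants. Per the labels, the polysomal mRNA came from 300 embryos and the total mRNA from 50, RNA was extracted with Trizol, polyA mRNA was used, and single reads of 36 bases were taken on an Illumina Genome Analyzer IIx. The authors gave 1 RPKM value (reads per kilobase of gene model, scaled to the mapped reads of the library) for each of 32313 Ensembl genes in each of 4 libraries. The submitters' processing notes name the Zv9 genome build. The aligner, the counting tool and the annotation release are not given in the sources used here. The embryos' genome sequence and gene coordinates were not used here, so genes are given by symbol and Ensembl identifier without a position. Symbols were joined by identifier for 20499 of the 32313 genes. Of these, 10366 are names in capitals, which are orthologue-type names and are printed as they stand.

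Low values in each library move in equal steps, as a whole number of reads plus 1 would, and the size of the step gives the depth. Reads behind the values were recovered in this way for 30358 genes, which is 93.9% of all genes and 84.6% of the 12590 genes that reached 3 RPKM in at least 1 library. The recovered depths were 15769466 mapped reads in wild-type polysomal, 22001382 in morphant polysomal, 24939984 in wild-type total and 21021420 in morphant total mRNA. For a gene model of 1 kb, 1 read is worth 0.0634, 0.0455, 0.0401 and 0.0476 RPKM in the same order. Where reads were recovered, a ratio has a 95% interval from the exact (Clopper-Pearson) binomial interval of the read counts, or for polysome association from the normal approximation on the log scale. These intervals cover counting error only. Polysomal libraries spread more than counting allows: of genes with 4 steps summed over a pair of libraries, 18.95% were split evenly between the polysomal libraries and 45.25% (95% interval 41.85 to 48.68) between the total libraries, so intervals of polysomal ratios are too narrow.

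Ratios are log2 of morphant over wild type after adding 0.5 to each RPKM, which understates differences of genes near the floor. Comparisons were made of polysomal mRNA, of total mRNA and of polysome association, which is the polysomal log2 ratio minus the total log2 ratio. Polysomal over total mRNA was also taken within each condition. A gene was above the floor with at least 3 RPKM in 1 of the libraries compared. For polysome association it needed at least 3 RPKM in both total libraries and in at least 1 polysomal library. Genes at least 2-fold higher or lower were counted. Each group has 1 library, so these comparisons leave no spread within a group, and no test between the groups is possible for them. How many genes counting error alone would carry past 2-fold was estimated by drawing reads for each gene at equal expression.

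For 35 gene lists (tissues and cell types of the embryo, parts of the translation machinery, mitochondrial and stress programmes), the median log2 ratio of the members above the floor was set against 10000 random lists of the same size matched on mean expression in 20 bins. Lists with fewer than 5 members above the floor have values only. The percentile among random lists serves as a description of these libraries. A list is given a direction where its percentile is at or below 2.5 or at or above 97.5. The named genes of a comparison are the gene of the targeted family, the 8 highest and the 8 lowest genes with a symbol beyond 2-fold, and from each list the up to 4 members farthest from 0. Genes without a symbol were counted and not named, and not every gene or list these rules select is given in the text. Comparisons, floor, fold, lists, the rule for named genes and most alternatives were fixed before the data were examined.

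The procedure was tested on simulated data with 50 genes set at each fold. It called 94% of genes at 2.5-fold, 98% at 3-fold, 100% at 4-fold and 0% at 1.5-fold, and 6 of 10445 unchanged genes passed 2-fold. The simulated reads varied by counting error only. The polysomal libraries spread more than that, so a larger share of unchanged genes may pass 2-fold in them. Alternatives tried were other scalings (median-of-ratios, upper-quartile, totals without the 50 most abundant genes), a pseudocount of 1, no floor, a floor of 12 RPKM, folds of 1.5 and 4, and the mean in place of the median of a list. An added requirement on the counting interval and a count without genes more than 4-fold higher in wild-type polysomal than in wild-type total mRNA were chosen after seeing the data. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.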

Results

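The series asks which transcripts depend on eIF3h, a subunit of the translation initiation complex eIF3, for their place on polysomes in the zebrafish embryo. A polysome is an mRNA carrying several ribosomes, and a morphant is an embryo injected with a morpholino, an antisense oligonucleotide, here against eif3ha. At about 24 hours after fertilization, RNA was taken from polysomal fractions of 300 embryos and from 50 whole embryos, each wild type or morphant. The 4 groups hold 1 library each, so no difference given here has a replicate check. The labels name no group injected with a control morpholino, so effects of injection cannot be told apart from loss of eIF3h. Depth was 15769466 mapped reads in wild-type and 22001382 in morphant polysomal mRNA, and 24939984 in wild-type and 21021420 in morphant total mRNA. Both polysomal libraries detected fewer genes at 3 RPKM or more (7737 in wild type, 7752 in morphants) than the total libraries did (11551 and 11657). Their 50 most abundant genes took 43.7% (wild type) and 38.8% (morphant) of the summed RPKM, against 24.2% and 24.1% in total mRNA.

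The first question is the level of the targeted gene itself. The feature named EIF3H (ENSDARG00000036116), which encodes eIF3h, stood at 6.33 RPKM in wild-type and 7.60 in morphant polysomal mRNA, and at 6.24 and 5.92 RPKM in total mRNA. Its log2 ratio of morphant to wild type was 0.25 (95% counting interval -0.15 to 0.70) in polysomal and -0.07 (-0.48 to 0.32) in total mRNA, so no difference was detectable at this depth. The annotation does not say which of the eif3h copies this feature is, and the labels do not say whether the morpholino blocks splicing or translation, so its mRNA level does not measure the knockdown. Among the 12 eIF3 subunits above the floor, none was 2-fold different in either fraction. Their median log2 ratio was -0.38 in polysomal mRNA (percentile 5.77 among random lists) and -0.14 in total mRNA (percentile 17.3), with EIF3K at -0.67 and EIF3B at 0.55 as the extremes in polysomal mRNA.

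In polysomal mRNA, a comparison that reflects transcript level as well as place on polysomes, lens and fast-muscle transcripts were the lowest in morphants. The 17 gamma M crystallins above the floor, structural proteins of the fish lens fibre, were more than 2-fold lower, as were 8 of 9 other lens crystallins. Transcripts of ribosomal proteins were lower as a group by less than 2-fold, at a median log2 ratio of -0.61 over 73 genes. To the other side, the pro-apoptotic gene pmaip1 and the posterior hox gene HOXC12 were the highest genes with a symbol, at log2 ratios of 2.86 and 1.87. Among 8261 genes above the floor, 145 were at least 2-fold higher in morphant polysomes and 340 at least 2-fold lower.

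The gamma M crystallins had a median log2 ratio of -3.32, below all of 10000 random lists matched on expression. Members included crygmxl2 (ENSDARG00000074001, -4.16), crygm2d17 (ENSDARG00000069817, -4.14) and crygm2d13 (ENSDARG00000057460, -4.08), the last at 13.0 RPKM in wild-type and 0.303 in morphant polysomes. These 17 of the 30 members in the files passed the floor through the wild-type polysomal library alone, which fixes their direction. Taken without a floor, the 30 members had 2539 reads in wild-type and 90 in morphant polysomal mRNA, and 23 of them had fewer reads per mapped read in morphants while 6 had no polysomal read. The 17 had 44 to 329 reads each in wild-type and 2 to 10 in morphant polysomes. Their median difference on reads was 35.2-fold lower (range 26.7 to 229.5-fold over the genes), and for crygmxl2, with 2 reads in morphants, the interval of the log2 read ratio ran from -10.89 to -5.98. In total mRNA the same genes had at most 7 reads in wild type and at most 4 in morphants, so none reached the floor there. The wild-type polysomal library therefore stands apart from the other 3 libraries for this family. These copies resemble each other in sequence, so the split of reads between them is uncertain and the family is best read as a whole.

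Other lens crystallins had a median of -2.05, also below all random lists. They included crybb1l2 (ENSDARG00000016793, -3.17) and cryba1l1 (ENSDARG00000032929, -2.79), the latter at 124 RPKM in wild-type and 17.5 in morphant polysomes against 9.63 and 8.65 in total mRNA. Of 6 lens genes that are not crystallins, 5 were more than 2-fold lower, with a median of -2.45 (percentile 0.01). They included MIP (ENSDARG00000013963, -2.97), the lens fibre water channel, and LIM2 (ENSDARG00000015445, -2.81), a lens fibre membrane protein, both above the floor in the wild-type polysomal library alone. In the retina and optic cup, by contrast, the median over 10 genes was 0.26 (percentile 95.8), with SIX3 (ENSDARG00000058008) at 0.89 and rbp4l (ENSDARG00000044684) at -2.04.

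Skeletal muscle transcripts had a median of -0.66 in polysomal mRNA (49 genes, 18 at least 2-fold lower and 1 higher), below all random lists. The lowest members were parvalbumins, the calcium buffers of fast muscle: pvalb4 (ENSDARG00000024433) at -3.64 and pvalb1 (ENSDARG00000037789) at -3.33. The pvalb1 transcript stood at 2972 RPKM in wild-type and 295 in morphant polysomes, against 19.5 and 59.4 RPKM in total mRNA, so here too the wild-type polysomal library stands apart. Transcripts of fast troponins were lower as well, such as TNNT3 (ENSDARG00000068457) at -2.02. The 4 heart muscle genes above the floor ranged from HAND2 at 0.85 to TNNC1 at -0.36. Actinodins, structural proteins of the larval fin fold, were lower in polysomes, with and3 (ENSDARG00000056873) at -3.54 and 18 RPKM in wild-type against 1.09 in morphant polysomes. In wild type, and3 was 68.0-fold higher in polysomal than in total mRNA. Actinodins belong to the list of periderm and epidermis, whose median of -0.04 over 31 genes lay at percentile 81.9.

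Neuronal transcripts had a median of -0.73 (24 genes, 7 at least 2-fold lower and none higher), below all random lists. They included the synaptic gene SNAP25 (ENSDARG00000058117, -1.96) and STMN2 (ENSDARG00000033234, -1.34), a regulator of growth-cone microtubules. Pigment-cell and neural-crest genes had a median of -0.41 (17 genes, 3 at least 2-fold lower, percentile 0.205). The lowest were the melanin-synthesis genes TYRP1 (ENSDARG00000029204, -2.16) and TYRP1 (ENSDARG00000056151, -2.07), and pmela, a component of the melanosome matrix, stood at -1.05.

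Of the 73 cytosolic ribosomal protein genes, 72 were below 0 in polysomal mRNA and 6 were at least 2-fold lower. The median of -0.61 lay below all random lists, whose own median was -0.30 at this high level of expression. RPL3 (ENSDARG00000003599) stood at -1.39, with 1911 RPKM in wild-type and 728 in morphant polysomes, and RPL10A (ENSDARG00000042905) at -1.37. Mitochondrial ribosomal proteins did not share this, with a median of -0.06 over 62 genes (percentile 24.1). Elongation factors, which carry translation past its start, had a median of -0.54 over 7 genes (percentile 2.68), with EEF1E1, a synthetase-complex protein, at 1.2 and EEF2 (ENSDARG00000035256) at -1.06. Initiation factors outside eIF3 had a median of 0.11 over 37 genes (percentile 98.1), none of them 2-fold different. Ribosome biogenesis factors were on the higher side, with 35 of 42 above 0 and a median of 0.23 (percentile 99.99).

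Among genes higher in morphant polysomes, pmaip1 (ENSDARG00000089307), a pro-apoptotic BH3-only gene, came first at 2.86, from 3 reads in wild type and 49 in morphants (interval of the log2 read ratio 1.92 to 5.88). Genes at least 2-fold higher also included the cell cycle inhibitor cdkn1a (ENSDARG00000076554, 1.45) and the pro-apoptotic bbc3 (ENSDARG00000069282, 1.45). The posterior hox genes HOXC12 (ENSDARG00000070352, 1.87) and HOXC13 (ENSDARG00000070353, 1.45) were also among the 8 highest, with MIA (ENSDARG00000052437, 1.57), the heparan sulphate proteoglycan GPC4 (ENSDARG00000015472, 1.54), the signalling peptide gene edn1 (ENSDARG00000036912, 1.51) and the pocket protein RBL2 (1.46). Hatching gland genes had a median of 0.43 (9 genes, 3 at least 2-fold higher, percentile 99.8), led by the hatching enzymes he1.2 (ENSDARG00000019122, 1.32) and he1.1 (ENSDARG00000023656, 1.18). Erythroid genes had a median of 0.36 (12 genes, percentile 99.8).

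**Figure D1:**
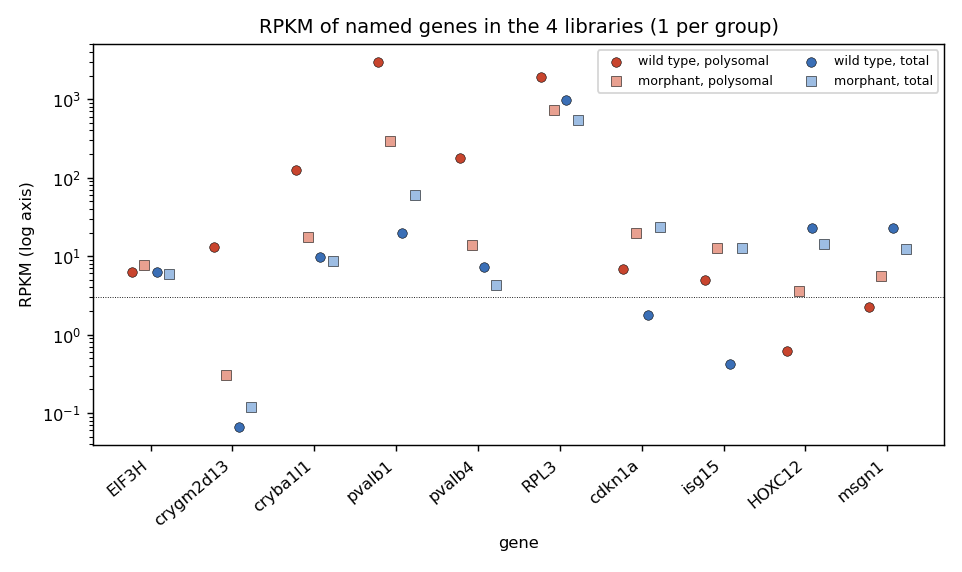
RPKM (log axis) of 10 named genes in the 4 libraries, 1 point per library; the dotted line marks 3 RPKM. For crygm2d13, cryba1l1, pvalb1 and pvalb4 the wild-type polysomal point lies above the other 3 points, while cdkn1a and isg15 are higher in morphants in both fractions.

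Polysomal differences of this size were more than counting error gives: it would carry 16 of 6374 genes with recovered reads past 2-fold, where 411 passed. The balance of higher and lower genes depends on scaling, since with totals taken without the 50 most abundant genes the median of all genes moved to 0.205 and the counts became 308 higher and 225 lower, and no median of a list given a direction here changed sign.

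In total mRNA, which measures transcript level in the whole embryo, isg15, the complement gene c4b and the cell cycle inhibitor cdkn1a were the highest genes with a symbol in morphants, and nervous-system and cell cycle transcripts were lower as groups by less than 2-fold. The interferon-induced isg15 (ENSDARG00000086374) came first, at a log2 ratio of 3.83, with 0.423 RPKM in wild type and 12.6 in morphants. Among 12154 genes above the floor, 174 were at least 2-fold higher in morphants and 82 at least 2-fold lower.

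Also among the 8 highest were cdkn1a at 3.41 (1.76 RPKM in wild type, 23.6 in morphants, interval of the log2 read ratio 3.52 to 3.99), PHLDA3 (ENSDARG00000037804), a repressor of Akt signalling, at 3.36, bbc3 at 3.07 and the initiator caspase casp8 (ENSDARG00000058325) at 3.04. In wild-type polysomal mRNA these transcripts were above their level in wild-type total mRNA, as for cdkn1a with 6.88 against 1.76 RPKM and PHLDA3 with 22.5 against 4.21. The complement gene c4b (ENSDARG00000038424, 3.55), ATXN1 (ENSDARG00000060862, 3.10) and RBL2 (ENSDARG00000045636, 3.07) completed the 8 highest. Of 4 interferon-response genes above the floor, isg15 and b2m (1.57), the light chain of class I histocompatibility molecules, were at least 2-fold higher. Genes of the integrated stress response, the programme set off by phosphorylation of eIF2, had a median of 0.12 over 34 genes (percentile 98.7, and 95.3 with a floor of 12 RPKM). They went both ways, with 6 at least 2-fold higher, among them atf5a (1.59) and atf4b (1.14), and the serine-synthesis enzyme PHGDH at -1.23.

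Neural progenitor genes had a median of -0.37 (35 genes), neuronal genes -0.30 (30 genes) and cell cycle genes -0.33 (44 genes, 41 of them below 0). Each median lay below all random lists, and no gene of these 3 lists was 2-fold different. Examples were nes (ENSDARG00000088805, -0.86), the intermediate filament of progenitors, the neuronal transcription factors ONECUT1 (-0.96) and NEUROD1 (-0.91), and the replication helicase subunits MCM3 (-0.91) and MCM5 (-0.81). Retina and optic cup genes had a median of -0.36 (14 genes, percentile 0.02, and 38.7 with a floor of 12 RPKM), with rx2 (ENSDARG00000040321), an eye-field transcription factor, at -1.42 and VAX2 at -1.08. Splicing factors and other RNA-binding proteins had a median of -0.20 over 61 genes, below all random lists, with SRSF1 (ENSDARG00000017843) at -0.94. The lowest genes with a symbol were dync1i2a (ENSDARG00000078386, -2.03), a dynein intermediate chain, g0s2 (ENSDARG00000078859, -1.96), an inhibitor of fat breakdown, the keratin krt1-19d (ENSDARG00000023082, -1.82), rsrp1 (ENSDARG00000030440, -1.76), SPON1 (ENSDARG00000023694, -1.58), the axonal adhesion gene cntn2 (ENSDARG00000000472, -1.57) and HSP90AA1 (ENSDARG00000024746, -1.46). Heat shock proteins, the last gene's family, had a median of -0.22 over 19 genes (percentile 0.57).

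Skin, muscle, pigment, myeloid and hatching gland transcripts were on the higher side in total mRNA. Periderm and epidermis genes had a median of 0.38 (33 genes, 29 above 0, 4 at least 2-fold higher and 1 lower), above all random lists, with the keratin krt97 at 1.37 and the calcium-binding icn at 1.25. Skeletal muscle genes had a median of 0.23 over 53 genes, above all random lists, with pvalb1 at 1.58 and TNNI2 at 1.23. Pigment-cell and neural-crest genes had a median of 0.23 over 19 genes (percentile 99.7, and 83.3 with a floor of 12 RPKM). Myeloid genes had a median of 0.67 over 6 genes (percentile 99.97), with the lysozyme gene lyz at 1.3. The 10 hatching gland genes had a median of 0.42 (percentile 99.98). Ribosomal protein genes, at -0.12 over 73 genes (percentile 14.7), and the 5 lens crystallins above the floor, at -0.04 (percentile 43.8), lay within the range of random lists.

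**Figure D2:**
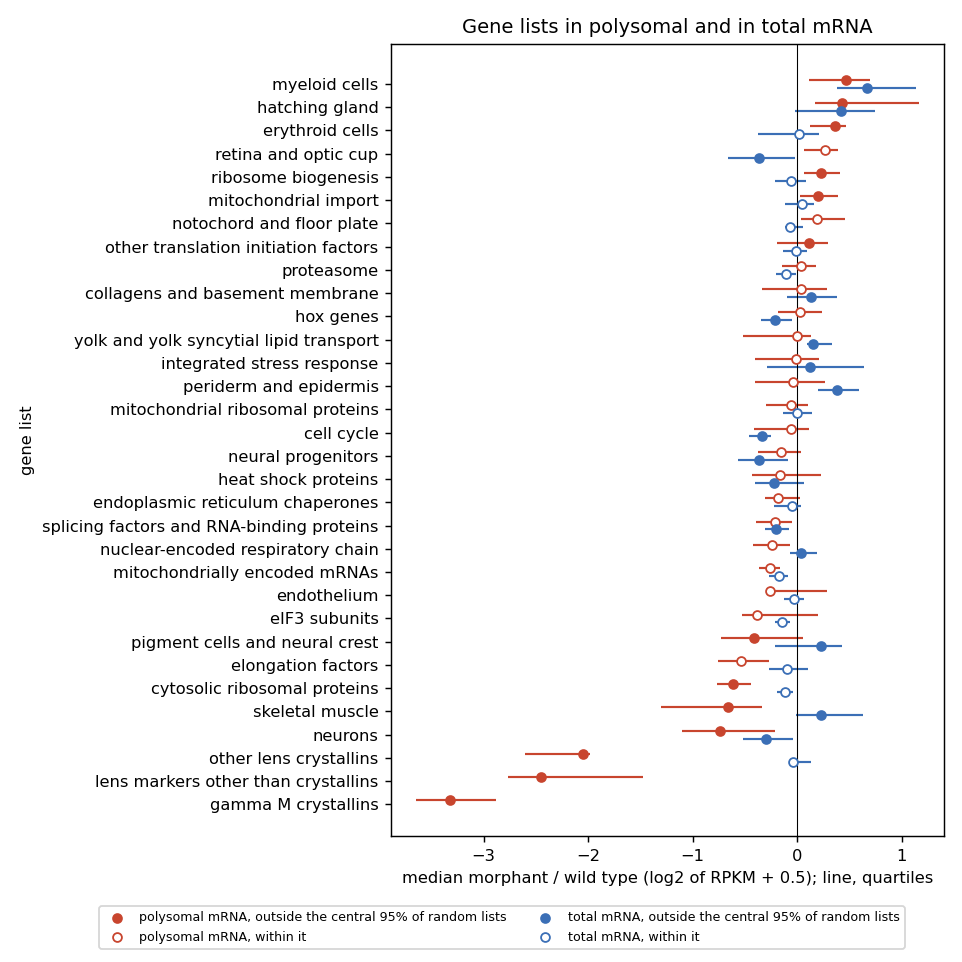
Median log2 ratio of morphant to wild type for the gene lists described in the text, in polysomal (red) and total mRNA (blue), with the quartiles as lines; filled points lie outside the central 95% of random lists matched on expression. Lens lists have the lowest polysomal medians, from -3.32 to -2.05, and myeloid genes lie above 0 in both fractions, at 0.47 and 0.67.

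Counting error would carry 16 of 10209 genes past 2-fold in total mRNA, where 238 passed. Of 7825 genes above the floor in both fractions, 49 were at least 2-fold higher in both (2.1 if the fractions were independent) and 13 at least 2-fold lower in both (0.969 if independent).

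Polysome association, the polysomal difference corrected for the difference in total mRNA, asks which transcripts were less or more on polysomes in morphants than their level accounts for. Lens crystallins and skeletal muscle genes again had the lowest medians of the lists, ribosomal protein, neuronal and respiratory chain transcripts were lower by less than 2-fold as groups, and the highest genes with a symbol were the hox genes HOXC12 and HOXC13. Of 46 skeletal muscle genes, 24 were at least 2-fold lower in association and 1 higher, with a median of -1.02. Among 7546 genes above the floor, 122 were at least 2-fold higher and 232 at least 2-fold lower.

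The lowest gene was pvalb1 at -4.91, and pvalb4 (-2.94), TNNT3 (-2.83) and TNNI2 (ENSDARG00000029069, -2.70), both parts of the fast troponin complex, were among the 8 lowest. Each stood higher in wild-type polysomal mRNA than in the other 3 libraries, as for TNNI2 with 1015 RPKM against 366 in morphant polysomes and 53.2 and 125 RPKM in wild-type and morphant total mRNA. Of 5 lens crystallins above the floor, 4 were at least 2-fold lower (median -2.63, below all random lists), including CRYGN (ENSDARG00000030411, -2.74), cryba1l1 (-2.65) and cryba1b (ENSDARG00000053875, -2.63). Gamma M crystallins had too few reads in total mRNA for an association value. Neuronal genes had a median of -0.40 (21 genes, 4 at least 2-fold lower), below all random lists, with INA, a neuronal intermediate filament, at -1.43 and STMN2 at -1.41. Periderm and epidermis genes had a median of -0.39 (28 genes, percentile 0.04) and pigment-cell and neural-crest genes -0.26 (14 genes, percentile 1.04, and 6.55 with a floor of 12 RPKM).

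Among housekeeping groups, 72 of 73 ribosomal protein genes were below 0 in association, with a median of -0.46, below all random lists, whose median was -0.25. RPL5 (ENSDARG00000020197) stood at -1.50 and RPLP1, a protein of the ribosomal stalk, at -1.14. Nuclear genes of the respiratory chain had a median of -0.30 (78 genes, 67 below 0), below all random lists, with cox6b1 (ENSDARG00000045230), a cytochrome c oxidase subunit, at -3.26 as the next lowest gene after pvalb1. In wild type, cox6b1 was 44.1-fold higher in polysomal than in total mRNA, so the wild-type polysomal library stands apart for it as for pvalb1. Ribosome biogenesis factors were on the higher side (34 of 42 above 0, median 0.28, above all random lists), with NAT10 at 0.86 and the box C/D methyltransferase FBL at 0.57. Cell cycle genes (median 0.22, 42 genes, percentile 99.99), neural progenitor genes (0.22, 30 genes, percentile 99.69), mitochondrial import (0.22, 22 genes, percentile 99.61) and proteasome subunits (0.16, 40 genes, percentile 99.85) were also above most random lists, with the mitotic cyclin CCNA2 at 0.99 and the progenitor factor SOX2 at 0.78. For cell cycle and neural progenitor genes the polysomal medians were -0.06 and -0.15 (percentiles 24.5 and 4.24), and their total medians were the lower ones, at -0.33 and -0.37.

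Of the 30 hox genes, 23 were above 0 in association, with a median of 0.32 (percentile 99.99). As a list they lay within the range of random lists in polysomal mRNA (median 0.03, percentile 46.6) and were lower in total mRNA (-0.21). HOXC12 (2.5) and HOXC13 (2.03) were the highest genes with a symbol, and after them came msgn1 (ENSDARG00000070546, 2.0) and tbx6 (ENSDARG00000011785, with a counting interval of 1.85 to 2.56), transcription factors of the presomitic mesoderm. HOXC12 stood at 0.615 RPKM in wild-type and 3.58 in morphant polysomes, against 22.6 and 14.4 RPKM in total mRNA, so its value rests on 7 and 64 polysomal reads. The keratin krt99 (ENSDARG00000019365, 1.80), the midbrain-hindbrain factor EN2 (ENSDARG00000038868, 1.69), the FGF-pathway inhibitor SPRY4 (ENSDARG00000068732, 1.45) and serbp1b (ENSDARG00000087421, 1.44) completed the 8 highest. Retina and optic cup genes had a median of 0.55 over 8 genes (percentile 99.97), although their mean was 0.12 (percentile 79.3) because rbp4l, a carrier of vitamin A, stood at -2.44.

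**Figure D3:**
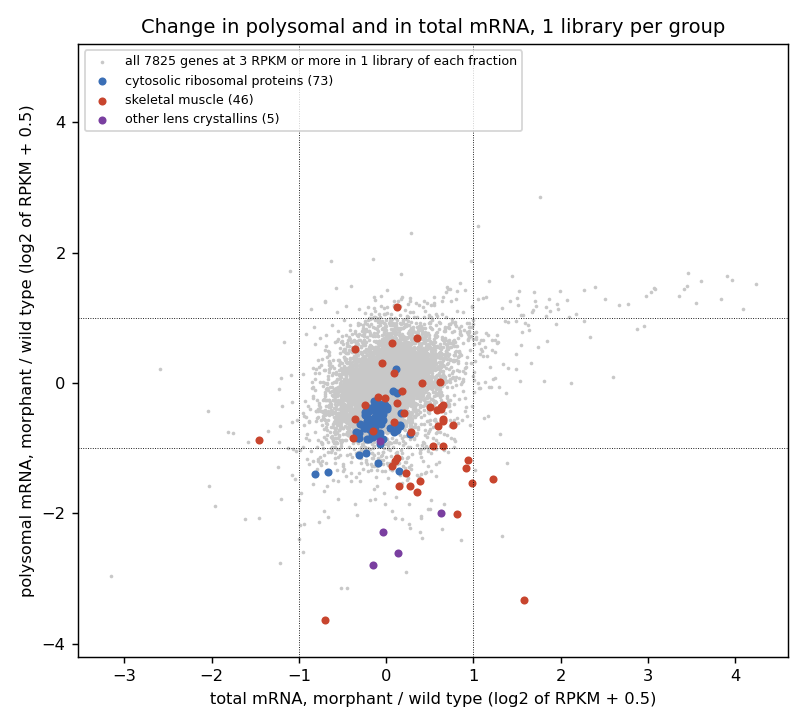
Log2 ratio of morphant to wild type in total mRNA (horizontal) and polysomal mRNA (vertical) for 7825 genes, with dotted lines at 2-fold and 3 gene lists in colour. Skeletal muscle genes lie mostly right of 0 and below it (medians 0.23 and -0.66), and all but 1 of the 73 ribosomal proteins lie below 0 in polysomal mRNA.

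Counting error would carry 15 of 5660 genes past 2-fold in association, where 282 passed, and 174 genes stayed at least 2-fold lower when genes more than 4-fold higher in wild-type polysomal than in wild-type total mRNA were left out. With totals taken without the 50 most abundant genes the median of all genes moved to 0.189 and the counts became 234 higher and 156 lower, and the medians of the lists given a direction kept their sign. Some of them came near 0, such as collagens and basement membrane (-0.02), pigment cells and neural crest (-0.07) and the respiratory chain (-0.10), and these are lower only relative to the random lists, which moved alike (percentiles 0.1, 1.15 and 0).

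Within each condition, polysomal over total mRNA gives the baseline of association. Transcripts of cytosolic ribosomal proteins, of the nuclear genes of the respiratory chain and of mitochondrial ribosomal proteins were enriched on polysomes in wild type. Their median log2 ratios were 1.74, 1.59 and 1.07, each above all random lists, whose medians were 1.32, 0.61 and 0.05. In morphants the same medians were 1.24, 1.25 and 0.98, against 1.005, 0.49 and 0.04 for random lists. Cytosolic ribosomal proteins lay at percentile 97.58 there. In wild type, eIF3 subunits (0.53, percentile 34.4), other initiation factors (0.02, percentile 21.0), elongation factors (0.70, percentile 60) and mitochondrially encoded mRNAs (0.94, percentile 12.2) lay within the range of random lists, and ribosome biogenesis genes below it (-0.64, percentile 0.05). The genes of yolk lipid transport were the least enriched, at -3.42 in wild type and -3.82 in morphants, below all random lists in both. For skeletal muscle the median was 1.18 in wild type, above all random lists, and 0.26 in morphants (percentile 44.8), and for the 5 lens crystallins it was 3.29 and 0.74. Hatching gland genes stood at -1.11 in wild type and -0.63 in morphants. Across 7546 genes, association in wild type and in morphants had a Spearman correlation of 0.908, and its standard deviation was 1.14 in wild type and 0.983 in morphants. Random lists were matched on mean expression and not on association in wild type. For lists enriched or depleted in wild type, such as the respiratory chain and ribosome biogenesis, a shift in association therefore cannot be told apart from this narrower spread. Across 5660 genes with a recovered gene model length, association correlated with length at -0.344 in wild type and -0.401 in morphants, and the difference between them at -0.0404. These correlations are across genes, which are not independent replicates.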

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

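Of the tests in this part, those of recruitment and of shared reads were chosen only after the result was seen. The list for the test of older embryos was drawn up after high association of msgn1 and tbx6 had been seen. That test is therefore not independent of these data, although both genes were left out. Skeletal muscle transcripts and pigment-cell and neural-crest transcripts are given here because the fractions went opposite ways between morphant and wild type, and with 1 library per group that difference was not tested. The median of skeletal muscle was -0.66 in polysomal and 0.23 in total mRNA, and its median in polysome association was -1.02. Pigment-cell and neural-crest genes had medians of -0.41 in polysomal and 0.23 in total mRNA, and -0.26 in association, but the total median fell to 0.10 with a floor of 12 RPKM (percentile 83.3) and the mean was 0.11 (percentile 87.1), both within the range of random lists.

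Skeletal muscle belongs to a wider pattern, in which many lens and fast-muscle transcripts were highest in the wild-type polysomal library. Within morphants, muscle transcripts as a list were not enriched in polysomal over total mRNA. Of 46 skeletal muscle genes, 10 were at least 2-fold higher and 7 at least 2-fold lower in morphant polysomal than in morphant total mRNA. Their median there was 0.26 (percentile 44.8), against 1.18 in wild type, above all random lists. Sharing of reads between crystallin copies is argued against as the whole cause, since reads moved between copies stay in the family, yet the summed polysomal reads of all 30 gamma M crystallins, taken without a floor, had a log2 ratio of -5.30 where shared reads need one near 0. Loading in wild type of transcripts already present in total mRNA stays open. The wild-type polysomal/total fold was taken with total mRNA held at no fewer than 3 reads. Its median over genes was 54.6 for the 17 gamma M crystallins. For the 31 other lens and muscle genes at least 2-fold lower in morphant polysomes it was 9.81, and both sets were chosen on the outcome. Among the 31 it was 10.3 for 8 other lens crystallins, 9.28 for 18 muscle genes and 22.3 for 5 lens genes that are not crystallins, 3 of them above 21.7. The most enriched ribosomal protein, RPL29, stood at 7.23, and 21.7 is 3 times that. Of 12 genes outside these lists above 21.7, 9 were themselves at least 2-fold lower in morphant polysomes, so the pattern is not confined to lens and muscle. Those with a symbol were and3 (68.0), and2 (63.3), SLC25A4 (55.3), cox4i1l (46.4), cox6b1 (44.1) and FABP1 (28.1). The other 3 (FOS, fkbp16 and tcnbb) reached at most 40.3. Older embryos in the wild-type polysomal pool may also account for the pattern, and the test of it did not decide: tailbud and presomitic mesoderm genes, which fade as somites finish forming, in a list without msgn1 and tbx6, whose high values had been seen, had a median association of 0.32 at percentile 97.23 (7 genes), just under the level set for that explanation, but in polysomal mRNA itself the median was 0.17 at percentile 86.4, and the list was lower in total mRNA (-0.46). Neither can be told apart from an effect of the knockdown or of the injection, which was not tested.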

How the results depend on the processing

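No paired analysis was possible because each group has 1 library. Medians of lists given a direction, and the highest and lowest genes of each comparison, kept their sign under every alternative run: 273 list values kept their place outside the central 95% of random lists and 14 did not, and all 200 values of the single genes stayed beyond 2-fold or, for EIF3H, within it. EIF3H in polysomal mRNA stayed between 0.23 and 0.46. A scaling to equal summed RPKM was not run. The sums were 785147 in wild-type and 614738 in morphant polysomal mRNA, and 426870 and 418782 in total mRNA. Equal sums would raise polysomal and association ratios, so the smaller negative medians might not keep their sign. Counts of genes beyond 2-fold depended on the floor and the fold by construction, since these set which genes can be counted. Without a floor, polysomal counts went from 145 higher and 340 lower to 280 and 549, total counts from 174 and 82 to 319 and 149, and association counts from 122 and 232 to 494 and 932. With a floor of 12 RPKM they were 58 and 161, 83 and 29, and 23 and 94. At 1.5-fold they were 657 and 905, 678 and 519, and 537 and 639, and at 4-fold 3 and 76, 39 and 7, and 5 and 29. With totals taken without the 50 most abundant genes, polysomal counts became 308 and 225 and association counts 234 and 156. The higher genes were then 57.8% of polysomal calls in place of 29.9%, and 60% of association calls in place of 34.5%. The genes left had a larger summed RPKM in wild-type than in morphant polysomal mRNA (scaling factors 1.218 and 1.038), which moved the ratios up. Median-of-ratios scaling (154 and 334 polysomal), upper-quartile scaling (170 and 324) and a pseudocount of 1 (110 and 289) kept every count within 1.5 times. After the data were seen, genes whose counting interval includes 1 were also left out (144 and 322 polysomal, 166 and 72 total), as were genes more than 4-fold higher in wild-type polysomal than in wild-type total mRNA (229 lower in polysomal mRNA and 174 lower in association). Depth limits genes near the floor, where 3 RPKM is few reads for a short gene, and most of all in the wild-type polysomal library, the shallowest.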

Other observations

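Of the tests in this part, those of mixed RNA and of transcript abundance were chosen only after the result was seen. Notochord and floor plate genes had a median log2 ratio of 0.19 (17 genes, percentile 96.3 among random lists) and -0.07 in total mRNA (percentile 26.2), and in association 0.22 (percentile 97.9, and 88.3 with a floor of 12 RPKM), with the notochord collagen col8a1a highest at 1.32 and FOXA2, a floor plate factor, at 0.90. Collagens and basement membrane genes had a median of 0.13 in total mRNA (45 genes, percentile 99.65, and 95.7 for the mean) and -0.22 in association (33 genes, percentile 0.26, and 2.75 for the mean), where the type I collagens COL1A1 (-1.44) and col1a1a (-1.05) were at least 2-fold lower. Yolk lipid transport genes had a median of 0.15 in total mRNA (23 genes, percentile 99.2) and -0.29 in association (percentile 4.41), with FABP1, a fatty acid binding protein, at -2.18. In wild type, FABP1 was 28.1-fold higher in polysomal than in total mRNA. Endothelial genes stayed within the range of random lists in polysomal mRNA (-0.26, percentile 9.85) and total mRNA (-0.04, percentile 44.6). Erythroid genes had a median of 0.02 in total mRNA (percentile 69.4) and 0.29 in association (11 genes, percentile 98.6, and 96.7 with a floor of 12 RPKM), where the blood transcription factor TAL1 stood at 1.14. Myeloid genes had a polysomal median of 0.47 (6 genes, percentile 99.1, and 95.2 for the mean). Total mRNA of hox genes was lower, with a median of -0.21 (34 genes, percentile 0.08, and 6.25 with a floor of 12 RPKM), and tailbud and presomitic mesoderm genes, a list drawn up later without msgn1 and tbx6, had -0.46 there (12 genes, below all random lists).

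Among housekeeping and stress genes, mitochondrially encoded mRNAs had medians of -0.26 in polysomal and -0.17 in total mRNA (13 genes, percentiles 63.0 and 13.7). Nuclear genes of the respiratory chain had a polysomal median of -0.24 (80 genes, percentile 3.46), with cox4i1l at -3.20, and mitochondrial import genes one of 0.20 (22 genes, percentile 99.1), with TIMM17A at 0.62. In wild type, cox4i1l was 46.4-fold higher in polysomal than in total mRNA, where it had 2 reads. Endoplasmic reticulum chaperones had a polysomal median of -0.19 (24 genes, percentile 4.18), with HSP90B1 at -1.50 and CALR at -1.11. Heat shock proteins had -0.16 (18 genes, percentile 16.1), with the small heat shock gene hspb9 at -2.06. The integrated stress response had a polysomal median of -0.01 (28 genes, percentile 44.6), with atf5b at 1.31 and nupr1a at 1.05. Proteasome subunits had 0.04 (40 genes, percentile 94.9) and splicing factors -0.21 (62 genes, percentile 4.46). The interferon-response genes isg15 (1.28) and b2m (1.05) were at least 2-fold higher in polysomal mRNA as well.

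Some genes higher in morphant total mRNA, such as cdkn1a, PHLDA3 and casp8, were above their wild-type total level in the wild-type polysomal library. A candidate explanation is morphant RNA mixed into that library, and the share it would need was computed for each gene from its ratio in total mRNA. That share was 33.6% (bootstrap SE 2.95) for 120 genes higher in morphant total mRNA and 48.9% (SE 14.5) for 32 genes lower. The difference of 15.3 points (SE 14.8) does not decide. The genes were picked on the same total mRNA ratio that gives the share, which can raise the share above 0 without mixing. The share also takes loading onto polysomes as equal in both conditions, and its SE is over genes, not libraries. The shares vary widely from gene to gene, with quartiles of 24.4% and 69.6% for the higher genes and -19.7% and 78.9% for the lower. A share below 0 was needed for 7 of the 120 and 10 of the 32, and one above 100% for 16 and 5. Noise in single libraries or unequal loading can put shares outside this range even with mixing, so these counts do not decide either. Mixing alone cannot account for those lens and muscle transcripts that were higher in the wild-type polysomal library than in every other. Not all were, since 8 of 49 skeletal muscle genes had a polysomal log2 ratio above 0. For transcripts such as cdkn1a, a difference in loading onto polysomes in morphants cannot be told apart from mixing here. The 1 wild-type polysomal library has no replicate, and a difference in loading was not tested.

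Ribosomal protein transcripts were lower in morphant polysomes, and so were other transcripts of like abundance. Mean abundance over the 4 libraries as the whole cause is argued against. Each of the 73 was set against the 10 genes of other kinds nearest in that mean. The median difference was -0.28 (95% bootstrap interval over genes -0.34 to -0.21). Of the 73, 64 were lower than their neighbours, whose own median was -0.31. The level of ribosomal protein transcripts in wild-type polysomes alone was not matched and stays open as a cause. Length of the gene models could not be tested, because a length was recovered for 1.4% of these genes and the test needs 80%. An effect of the eif3ha knockdown on these transcripts, which the groups name, stays open and was not tested.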
